A study of Mus musculus with 9 samples.

How the data were processed

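Chromatin immunoprecipitation with sequencing (ChIP-seq), in which DNA bound by a protein is pulled down with an antibody and sequenced, was done in Sv129 mouse embryonic stem cells. The 9 samples were 2 KDM6A immunoprecipitations of control cells, 2 of cells given 0.12 µM MTX for 24 h, 1 IgG immunoprecipitation of MTX cells (a nonspecific antibody that measures background), and 4 inputs. Groups and replicate numbers were taken from the sample titles. Interval lists of the 4 KDM6A libraries and the IgG library were analysed, and none was used for the inputs. Libraries were amplified over 30 cycles, per the labels' protocols. Nothing in the labels says whether libraries of a group came from separate cultures, so spreads between them may be technical.

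Reads were aligned with Bowtie2 to mm10, per the submitters' processing notes, and no version was given there. The program that called the intervals is not given in the sources used here. Each list had 8 columns and no header, and every interval started and ended on a 200 bp grid. Intervals were called per library and not on pooled libraries, since each deposited list held its own positions and values. The deposited counts are whole reads per interval, one for the immunoprecipitation and one for a background library, without normalization. The deposited fold is the ratio of immunoprecipitated to background reads times 1 constant per list, which was between 1.04 and 1.32 and which stands for the ratio of background to immunoprecipitated depth. The deposited p-value is the upper tail of a Poisson distribution with the scaled background as its mean: recomputed values matched for 100% of the intervals above fold 1, within 0.01 on the log10 scale. The last column holds adjusted p-values, as deposited. In 6 intervals of control library 1 the background count was 0 and the deposited fold was computed with 0.25 in its place. Lists held intervals with an adjusted p of 1 and folds under 1, so they were not filtered on either. The IgG library and MTX library 1 had the same background counts in 52 of the 52 intervals they had in common, which no pair of KDM6A libraries did. Totals in the lists cover only the reads within intervals, so the full depth of each library is unknown.

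All intervals were kept. Coordinates are mm10, counted from 1. Overlap of at least 1 bp was counted in both directions for each of the 10 pairs of libraries, with the Jaccard index of covered bases. Intervals of the 4 KDM6A libraries that touched or overlapped were merged into regions. A region was called shared when all 4 libraries had it, control-only when both control and neither MTX library had it, and MTX-only in the reverse case. Chance levels came from 100 random shifts of each list around its own chromosomes, which keep interval widths and spacing. Shifts do not keep unmappable stretches or a list's own share of intervals at gene ends. With 2 libraries against 2 there are 3 splits, and an exact permutation test cannot give a p under 0.333, so no such test was run on counts of intervals and regions, which are set beside the shifted lists. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only.

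Genes came from a RefSeq table of the GRCm38.p6 assembly, the same build as mm10, with 21887 protein-coding genes on the main chromosomes. The table gives the span of a gene without strand, transcripts or exons. Windows within 1 kb of either end of a gene therefore replaced the planned promoters, and intervals were sorted by midpoint into gene ends, the inside of genes and the rest, in place of the planned classes of exons, introns and untranslated regions. In 15 gene lists fixed before the data were examined, members with an interval in a gene-end window were compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 75 tests (15 lists, 5 libraries). Of the list members, 3 imprinted genes were not found as protein-coding. Control-only and MTX-only genes were compared between each list and all other genes in the same way, adjusted over 15 lists. Genes are not replicates, and neighbouring receptor genes can share 1 interval, so these p-values describe the libraries and are too small for clustered families.

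The named genes are the 10 shared, 10 control-only and 10 MTX-only genes with the highest rank of their best gene-end interval in the library where it ranked lowest, with no interval that overlapped an IgG interval and without predicted symbols, then up to 4 members of each list and direction by the same rule, and Kdm6a, Uty and Kdm6b. Ranks were by the deposited p, then fold. This rule was fixed before the data were examined, and any other gene named was chosen after its values were seen. Some genes that the rule or a list takes in are not reported here.

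Read counts at the shared regions were summed per library and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, Benjamini-Hochberg adjustment), with the log of the scaled background count plus 0.5 as an offset. This test was added after the files were seen to hold counts. limma 3.58.1 on the log2 ratio with pseudocounts of 0.5 and 2 was an alternative. Intervals and lists were processed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Simulated data for control against MTX were made from the real backgrounds at 2132 regions, with 1 dispersion for all of them. In these data edgeR recovered 68 of 100 regions changed 2-fold and 100 of 100 changed 4-fold, with 3 calls among 1932 unchanged regions. Median log2 folds over background at these regions were 0.28 to 0.41, so complete loss at a typical region would be a change of less than 2-fold. Such smaller changes were not simulated, and the recovery rates do not cover them. The overlap code recovered 300 of 300 planted control-only, 200 of 200 planted MTX-only and 100 of 100 planted shared regions.

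Alternatives chosen before the data were examined were the better 50% of each list, lists of equal length, overlap of at least 50% of the shorter interval, merging up to 500 bp, removal of intervals that overlap IgG, windows of 3 kb or from 2 kb outside to 0.5 kb inside a gene, autosomes and X alone, and each KDM6A library left out. A replicate block had been planned for control-only and MTX-only regions and for gene lists in case the files gave a quantity per region in every library, which they give only for shared regions. Those added afterwards were an adjusted p under 0.05 with a fold above 1, removal of chromosome 11, windows over the whole gene, and all settings of the fold test, its replicate block included.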

Results

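The series profiled KDM6A, a histone demethylase also called UTX, in Sv129 mouse embryonic stem cells with and without MTX. The comparison asks where KDM6A lay on the genome in control cells and whether that changed after 24 h in 0.12 µM MTX. There were 2 control and 2 MTX KDM6A libraries and 1 IgG library from MTX cells. The lists of control libraries 1 and 2 held 44838 and 21228 intervals, those of MTX libraries 1 and 2 held 24177 and 28976, and the IgG list held 22843. Reads within intervals numbered 4041853 and 3348266 in the control libraries, 3251202 and 4192029 in the MTX libraries and 3513697 in IgG, over 138, 90.4, 90.2, 114 and 95.1 Mb. A typical interval was shallow, with a median of 79 to 130 immunoprecipitated reads per library and a median deposited fold of 1.39 to 1.62 over background. The number of intervals was 33033 ± 16695 in control and 26577 ± 3393 in MTX cells (SD, n = 2), a difference smaller than the spread between the control libraries.

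Of the genes with an interval at a gene end in all 4 KDM6A libraries, 19 had no interval that overlapped IgG and no predicted symbol, and these were led by olfactory receptors, a multigene family of odorant receptors, on chromosome 11, where intervals were dense in every library, IgG included. The first of the named genes was Olfr389 (gene at 73776387 to 73780589), with a fold of 1.46 ± 0.21 in control and 1.87 ± 0.42 in MTX cells (SD, n = 2). Olfr381, in the same cluster (gene at 73485887 to 73486822), had folds of 1.40 ± 0.07 and 1.34 ± 0.19. Etfrf1 on chromosome 6 had 1.46 ± 0.48 and 1.63 ± 0.10, and Klhl7 on chromosome 5 had 1.67 ± 0.61 and 1.65 ± 0.38. At Klhl7 the MTX 1 interval (24099401 to 24102000) lay at the other end of the gene from those of the other 3 libraries, and in all, 5 of the 10 genes and 140 of the 213 shared genes had 1 end with an interval of every library. Olfr968, Abca16, Olfr878, H2-Q1, a major histocompatibility class I gene, Ubd, a ubiquitin-like modifier, and Taco1 completed the 10, with control means of 1.21 to 1.79 and MTX means of 1.03 to 1.57. Differences of these folds between groups were not tested, and an exact permutation test of 2 against 2 cannot go below p = 0.333. Reads of such multigene families can map to more than 1 copy, so intervals at olfactory, vomeronasal and histocompatibility genes are uncertain. A gene counted as shared even where an interval had a high deposited adjusted p (Poisson test). The highest per gene was above 0.05 at Taco1 (0.439, MTX 1), H2-Q1 (0.189, MTX 2), Ubd (0.18, control 1) and Olfr878 (0.119, MTX 1). It was also above 0.05 at Olfr968 (0.0857, MTX 1), Abca16 (0.077, MTX 2) and Etfrf1 (0.0726, control 2). It was below 0.05 at Klhl7 (0.0368, control 1), Olfr381 (0.0143, MTX 1) and Olfr389 (7.45e-06, control 1).

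Of 21887 protein-coding genes, 4412 and 1691 had a gene-end interval in control libraries 1 and 2, 2944 and 2029 in MTX libraries 1 and 2, and 2285 in IgG. All 4 KDM6A libraries shared 213 genes, against 41.2 (SD 12) over 100 random shifts of the lists. Among all intervals, the 4 libraries merged into 82424 regions, of which 62498 (75.8%) were in 1 library and 2132 in all 4, against 385 ± 41.5 for shifted lists, a ratio of 5.54. Covered bases overlapped by 2.54 to 2.95 times the shifted level in the 6 pairs of KDM6A libraries. The mean ratio was 2.69 for the pairs within a group and 2.83 for the pairs between groups, so libraries of 1 group did not overlap more than libraries of different groups. IgG overlapped the KDM6A libraries by 3.00 to 3.50 times the shifted level, with a mean of 3.16 beside 2.78 for the pairs of KDM6A libraries. By this ratio the KDM6A libraries did not overlap each other more than they overlapped IgG, which is 1 library. The overlap between KDM6A lists is therefore no sign of sites specific to KDM6A. The shared class held 178 regions in the better 50% of each list, 22.1 times the shifted level, and 667 without intervals that overlap IgG, 10.1 times.

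Genes with intervals in both control libraries and neither MTX library were led by Atoh8, a basic helix-loop-helix transcription factor, on chromosome 6 (gene at 72206174 to 72235780). Its intervals lay at 72204001 to 72205400 in control 1 and at 72206401 to 72209200 in control 2. Both were at 1 end of the gene but did not overlap, and the mean fold over these 2 sites was 2.87 ± 0.57 (SD, n = 2). Abi2, an adaptor of actin regulation on chromosome 1, followed with 1.69 ± 0.13, but its intervals were part of a merged region of all 4 libraries (60458801 to 60488200), with log2 folds of 0.68 and 0.32 in control and 0.63 and 0.35 in MTX cells. Laptm4b, a lysosomal membrane protein on chromosome 15, had 1.71 ± 0.04, Cyp2r1, a vitamin D hydroxylase on chromosome 7, had 1.61 ± 0.00457, and Cst10, a cystatin gene on chromosome 2, had 2.11 ± 0.06. The other 5 were receptor genes on chromosome 7: Vmn2r60, Vmn1r65 and Vmn2r76, which are vomeronasal (pheromone) receptors, and Olfr493 and Olfr608, with means of 1.90 to 2.91. The intervals of the control libraries lay at opposite ends of Laptm4b, Cst10 and Vmn2r60, so these means combine different sites, and MTX 2 had an interval in the merged regions at Cyp2r1 and Olfr493.

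MTX-only genes included Vapa, a membrane protein of the endoplasmic reticulum, on chromosome 17 (gene at 65580053 to 65616462), with folds of 2.15 in MTX 1 and 4.23 in MTX 2. Vapa also had an IgG interval at its other end, at 65616001 to 65619200, with a fold of 1.19. Stim2, a calcium sensor on chromosome 5, had folds of 2.35 and 2.27, Focad on chromosome 4 had 1.78 and 2.53 at opposite ends of the gene, and Dppa1 on chromosome 11, a gene named for its association with developmental pluripotency, had 2.81 and 1.65. The other 6 were receptor genes, of which Olfr798 on chromosome 10 led with 2.07 and 1.96, followed by Vmn1r15, Olfr954, Vmn1r5, Olfr806 and Olfr988. Absence here means that no interval of a library reached a gene end: at 57 of the 238 control-only and 55 of the 165 MTX-only genes, the other group had an interval in the same merged region. Among the genes named, this was control 1 at Stim2 and Olfr806 and both control libraries at Vmn1r5. Of the 238 control-only and 165 MTX-only genes, 161 and 112 had an interval of both libraries of the group at the same end. In 143 and 105 these intervals lay in the same merged region. At Vapa, Stim2 and Vmn1r5 the intervals of the MTX libraries lay at the same end but in different regions, so their folds belong to different sites.

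**Figure D1:**
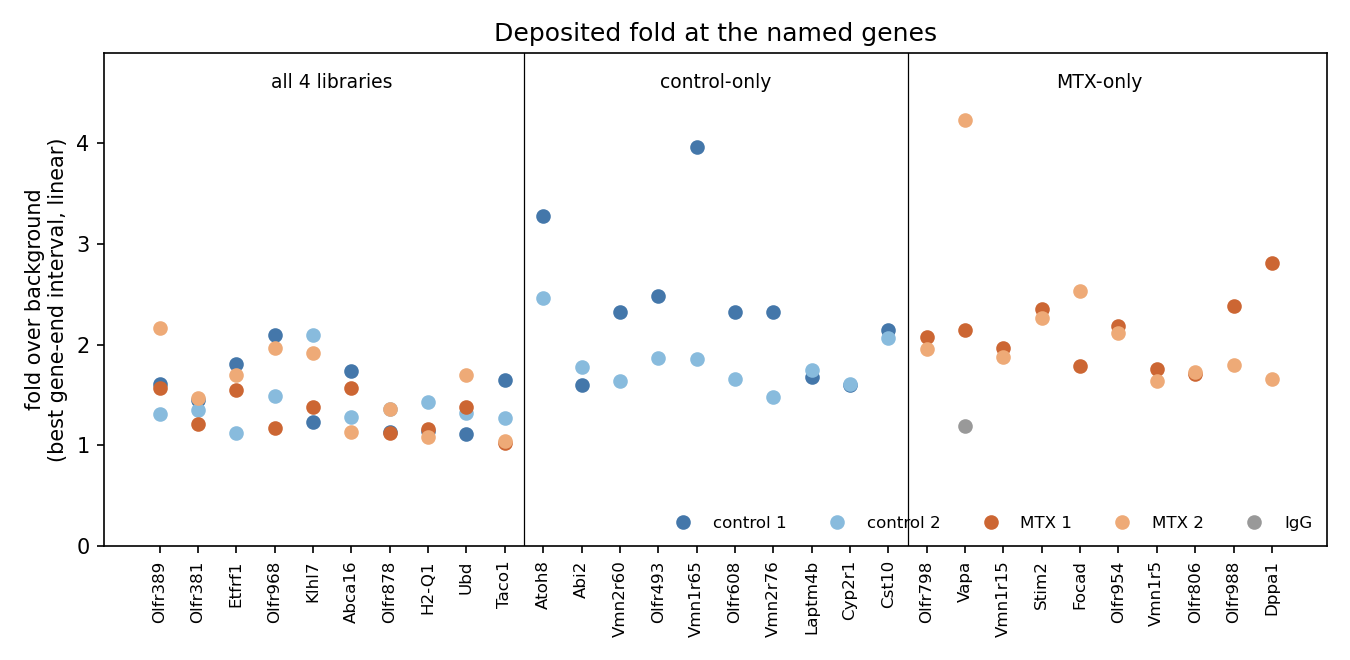
Deposited fold over background (linear axis) of the best gene-end interval at the 30 named genes, with 1 point per library that listed one. The 10 genes of all 4 libraries lie between folds of 1.02 and 2.16, and the highest value among the group-specific genes is 4.23 at Vapa in MTX 2.

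In all, 238 genes were control-only and 165 MTX-only, against 274 ± 29.0 and 210 ± 20.6 (SD) for shifted lists. Shifted lists do not keep a list's own share at gene ends, so these levels are approximate for genes. By region the counts were 2173 control-only, against 2136 ± 73.8, and 1684 MTX-only, against 1626 ± 67.3, or 1.02 and 1.04 times the shifted level. In the mixed pairs of libraries, 3090 regions were in control 1 and MTX 1 alone (1.35 times the shifted level), 1934 in control 2 and MTX 2 alone (1.24 times), 3354 in control 1 and MTX 2 alone (1.16 times) and 1244 in control 2 and MTX 1 alone (1.01 times). Averaged over both sides of a split, the ratio was 1.03 for control against MTX, 1.30 for libraries 1 against libraries 2 and 1.09 for the crossed split. The region counts fell to 918 control-only and 818 MTX-only in the better 50% of each list, but these were 1.48 and 1.70 times the shifted level there. The mean ratios of the splits were closer in that setting. They were 1.59 for control against MTX, 1.62 for libraries 1 against libraries 2 and 1.65 for the crossed split. With 1 library standing for its group the condition is looser, and control-only regions numbered 11482 without control 1 and 30776 without control 2, MTX-only regions 16346 without MTX 1 and 13512 without MTX 2.

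**Figure D2:**
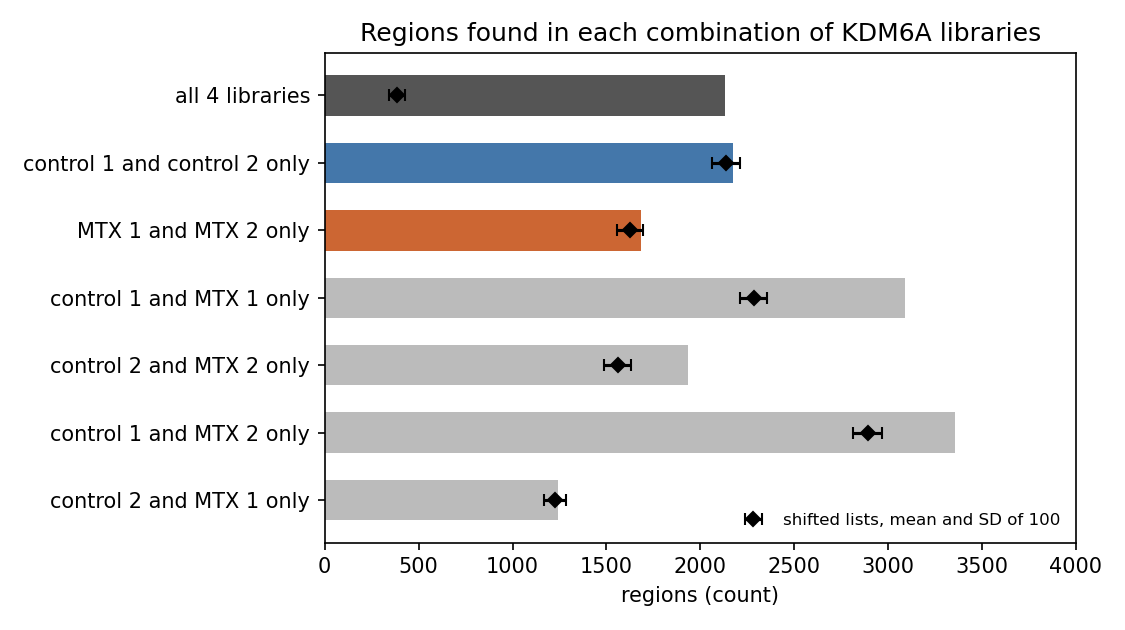
Number of regions in all 4 KDM6A libraries and in each exclusive pair (bars, linear axis from 0), with the mean and SD over 100 random shifts (diamonds). The control-only and MTX-only bars (2173 and 1684) end at the shifted means (2136 and 1626), whereas the 2132 regions of all 4 libraries exceed theirs (385).

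At the regions of all 4 libraries, the only ones with counts in every library, no region passed the test of MTX against control cells. Each count was summed over a library's own intervals, which need not cover the same bases. Sites listed in 1 group alone were not tested. edgeR called 0 of 2132 regions higher and 0 lower at an adjusted p under 0.05, with 83 regions under an unadjusted p of 0.05 and a smallest adjusted p of 1.00. The split by replicate number and the crossed split had more regions under the unadjusted threshold, 108 and 148, so the 83 are no sign of a change with MTX. limma also called 0, with 69 under the unadjusted threshold at a pseudocount of 0.5. Median log2 folds were 0.41 and 0.28 in the control and 0.34 and 0.34 in the MTX libraries. The median absolute difference between the groups was 0.15 on the log2 scale, beside a median SD between replicates of 0.17 in control and 0.15 in MTX cells.

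The gene for KDM6A itself, on the X chromosome (18160862 to 18279936), and Uty, its homolog on Y, had no gene-end interval in any of the 5 libraries. Only 2 to 20 intervals per library were listed on X, so this says little about either locus. Kdm6b, which encodes a related demethylase on chromosome 11, had an interval in MTX library 1 with a fold of 1.49 (161 against 116 reads, deposited adjusted p = 2.38e-06) and none in the others.

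IgG intervals lay at most of the regions shared by all 4 KDM6A libraries and at a minority of the others. Among the shared regions, 75.1% (exact 95% interval 73.2 to 76.9%) overlapped an IgG interval. Zfp281, a zinc finger factor of pluripotent cells, was the member of the pluripotency list with a gene-end interval in all 5 libraries. The share was 22.0% (20.2 to 23.8%) of control-only and 25.5% (23.5 to 27.7%) of MTX-only regions, and 10.9% (10.7 to 11.2%) of regions in 1 library. Control-only and MTX-only regions differed in this share by Fisher's exact test (two-sided, over regions, which are not replicates; odds ratio 0.820, p = 0.0103), and the IgG library came from MTX cells alone. Per library, 18.4% and 25.6% of control and 24.9% and 23.2% of MTX intervals overlapped IgG. Shared regions were also wider, with a median of 12200 bp against 5200 and 5400 bp in the group-specific classes.

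Intervals lay inside genes in 46.3 to 49.5% of cases, or 1.19 to 1.27 times the shifted level in all 5 libraries. Gene ends held 4.89% of intervals in control 1 and 5.86% in MTX 1, which was 1.42 and 1.64 times the shifted level, but 3.13% in control 2 and 2.64% in MTX 2, or 0.851 and 0.736 times, and 4.28% in IgG, or 1.23 times. These values differed between replicates of a group by more than between groups. For control 1 the ratio turned below 1 in lists of equal length (0.929), and for IgG it did so in the better 50% of the list (0.716). Chromosome 11 held 12.5% and 24.48% of control, 17.9% and 19.6% of MTX and 16.5% of IgG intervals, at 2.74 to 6.23 times the density of the other autosomes, and 44.5% of the regions shared by all 4 KDM6A libraries.

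**Figure D3:**
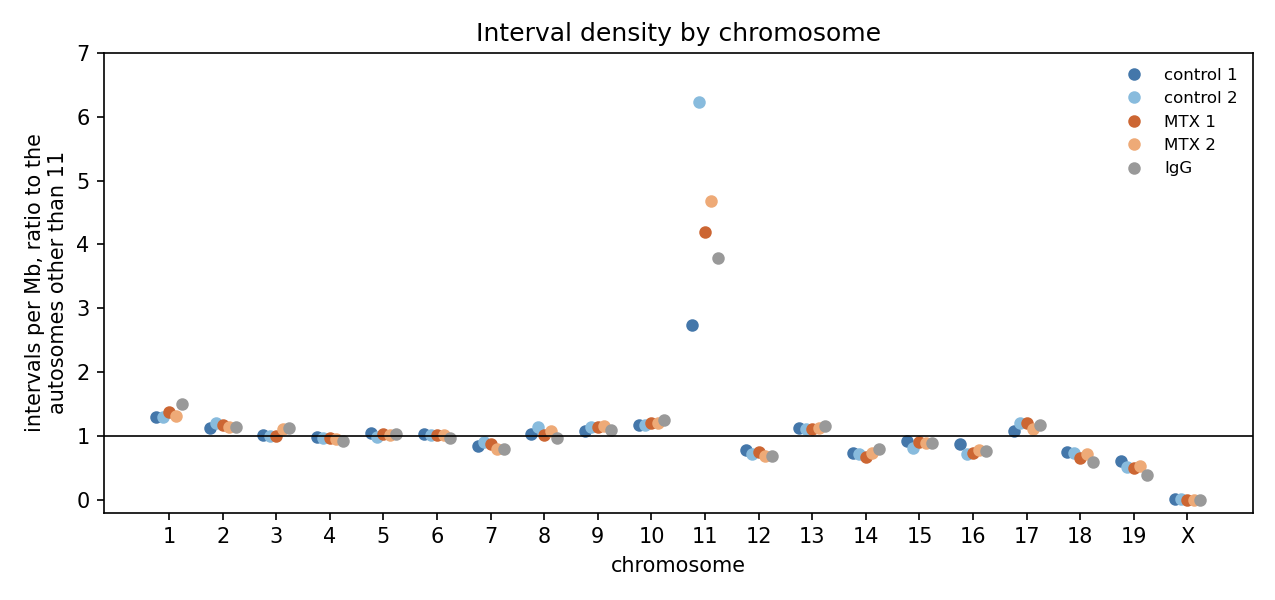
Intervals per Mb on each chromosome relative to the autosomes other than 11 (linear axis), with 1 point per library. Chromosome 11 lies between 2.74 and 6.23 in the 5 libraries, the other autosomes between 0.392 and 1.49, and X close to 0.

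Pluripotency genes, which maintain the embryonic stem cell state, carried gene-end intervals more often than other genes in control 1, MTX 1 and IgG, but not in control 2 or MTX 2. Of 30 members, 15 had an interval in control 1 (log2 odds ratio 1.99, adjusted p = 0.00313), 17 in MTX 1 (3.07, adjusted p = 5.78e-07) and 15 in IgG (3.11, adjusted p = 9.21e-07), against 3 in control 2 and 4 in MTX 2 (all by Fisher's exact test). Klf5, Nanog, Nr5a2, Tbx3, Tet1, Tet2, Tfcp2l1 and Zfp281 had one in control 1, MTX 1 and IgG. Folds there ran from 0.814 at Tfcp2l1 in IgG to 3.16 at Nr5a2 in control 1. Nanog, a core transcription factor of the network, had 1.02 in control 1, 1.34 in MTX 1 and 1.11 in IgG. Tet2, a DNA demethylation enzyme, had 2.20 and 1.38 in control 1 and MTX 1 at 1 end and 1.20 in IgG at the opposite end, and the IgG interval of Tfcp2l1 also lay at the opposite end. Control 1 no longer passed the test, while MTX 1 did, in 3 settings. These were without intervals that overlap IgG (log2 odds ratios 0.40 and 2.52), in lists of equal length (1.32 and 3.06) and with interval midpoints within the windows (1.41 and 2.56). Neither library passed in the better 50% of each list, which holds fewer intervals, though the ratios stayed above 0 (1.20 and 1.35).

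Olfactory receptor genes stood above other genes in control 2, MTX 2 and IgG: 190 of 1110 in control 2 (log2 odds ratio 1.41, adjusted p = 9.75e-25), 232 in MTX 2 (1.48, adjusted p = 7.81e-32) and 201 in IgG (0.99, adjusted p = 7.26e-14), all by Fisher's exact test, against 241 in control 1 and 146 in MTX 1, where the test was not passed. Control 1 passed in lists of equal length (1.36, exact test, adjusted p = 1.06e-19), in the better 50% (1.33), at a deposited adjusted p under 0.05 (0.60) and in windows from 2 kb outside to 0.5 kb inside a gene (0.37), and MTX 1 in the better 50% (1.00) and at an adjusted p under 0.05 (0.42). With windows over whole genes the olfactory receptors were below other genes in control 1 (-1.33), control 2 (-0.53), MTX 1 (-1.46), MTX 2 (-0.44) and IgG (-0.52). p53 targets and DNA damage genes passed in control 1, with 16 of 35 members (log2 odds ratio 1.75, exact test, adjusted p = 0.0101), and had 10 members in MTX 1, 2 in control 2, 3 in MTX 2 and 7 in IgG. Control 1 did not pass in the better 50% of each list (1.58), in lists of equal length (1.08) or without intervals that overlap IgG (1.58, exact test, adjusted p = 0.0578). In all, 7 of 75 tests passed after adjustment and 15 before it, and with windows over whole genes 22 passed.

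**Figure D4:**
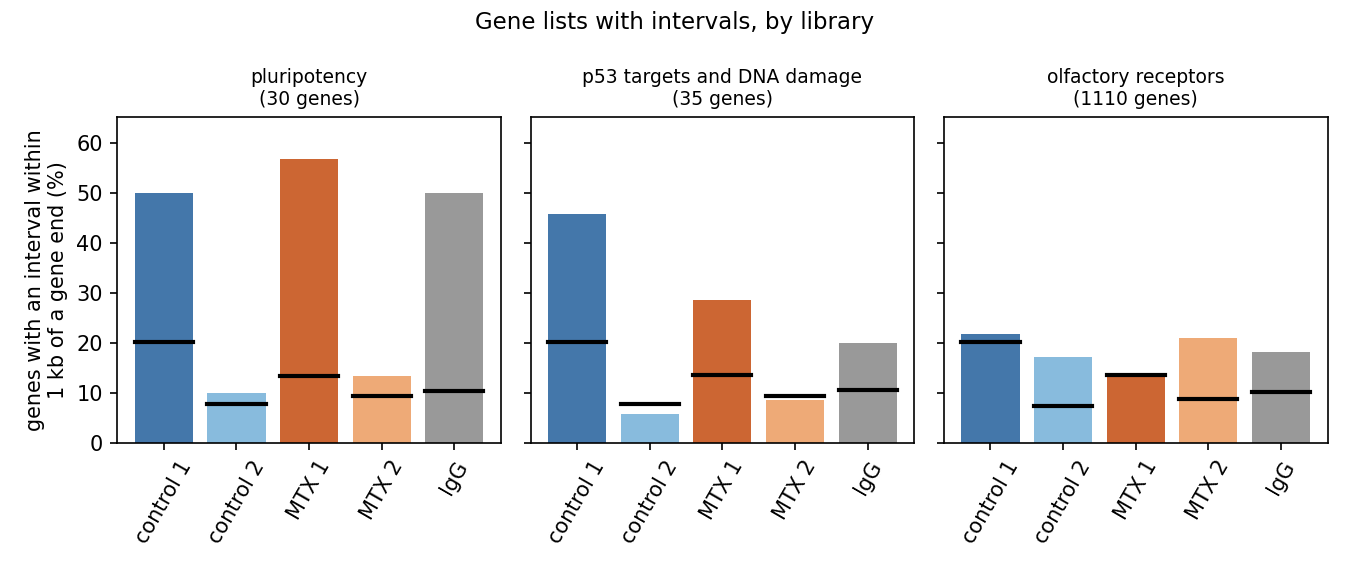
Percent of genes with an interval within 1 kb of a gene end for 3 gene lists (bars, axis from 0), with the percent of all other protein-coding genes in the same library (black lines). Pluripotency genes reach 50, 56.7 and 50% in control 1, MTX 1 and IgG, against 10 and 13.3% in control 2 and MTX 2.

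None of the other 12 lists passed in any library with windows at gene ends. With windows over whole genes, 13 tests of 7 of these lists passed, 6 above and 7 below other genes, among them germline genes above in control 1, control 2 and MTX 2 and ribosomal protein genes below in control 2, MTX 1 and MTX 2. Counts follow in the order control 1, control 2, MTX 1, MTX 2 and IgG. The KMT2C/KMT2D complex with the KDM6 demethylases, the complex KDM6A belongs to, had 2, 1, 3, 0 and 2 of 12 genes, and Polycomb repressive complex 2, which places the histone mark that KDM6 enzymes remove, had 5, 2, 2, 2 and 4 of 12. Hox cluster genes, the patterning genes of the body axis, had 7, 1, 10, 0 and 4 of 39. Neural tube closure genes had 15, 1, 9, 3 and 7 of 62, neural progenitor and patterning genes 5, 0, 5, 3 and 2 of 49, and Wnt pathway genes 12, 1, 9, 3 and 5 of 61. Folate and one-carbon metabolism genes had 14, 4, 10, 5 and 5 of 42. Mesoderm and endoderm markers had 7, 3, 3, 1 and 5 of 41, germline genes 8, 2, 2, 2 and 2 of 20, imprinted genes 6, 3, 3, 0 and 4 of 27, and ribosomal protein genes 23, 2, 12, 2 and 11 of 75. Fibroblast markers, included for feeder cells, had 1, 1, 0, 1 and 0 of 20.

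Outside the olfactory receptors, 14 lists had at most 1 control-only or MTX-only gene each. Ncoa6, a subunit of the KMT2C/KMT2D complex, was control-only with a fold of 1.45 in control 1 and 1.65 in control 2. Slc46a1, the proton-coupled folate transporter, was control-only with folds of 2.01 and 0.898, the second with a deposited adjusted p of 1. Cer1, a secreted Nodal antagonist, had 1.54 and 1.28, at opposite ends of the gene as for Slc46a1 and with an MTX 1 interval in the merged region, and Sycp2, a synaptonemal complex gene, had 0.975 and 1.69. Neurod4, a neural transcription factor, was the MTX-only member of the neural progenitor list. Among 1110 olfactory receptors 31 were control-only and 16 MTX-only, beside 207 and 149 of the other genes (Fisher's exact p = 0.346). With at most 1 such gene, the other 14 lists could not pass this test, and 0 of 15 lists were under an adjusted or an unadjusted p of 0.05. The olfactory list passed without control 2 toward MTX-only, with 4.93% of control-only and 11.6% of MTX-only genes (exact test, adjusted p = 0.000816), and without MTX 2 toward control-only, with 12.7% and 4.81% (exact test, adjusted p = 4.65e-06).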

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

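The tests of explanations in this part, and the counts over mixed splits behind them, were chosen after the result was seen, whereas the list tests and the settings with the better 50% of each list or without intervals that overlap IgG were planned. Background reads, which enter the comparisons of the groups only as the level that folds and the fold test are scaled by, were denser in the intervals of chromosome 11 than in those of the other autosomes, which marked them for a closer look. The ratio of background reads per kb was 1.26 in control 1, 1.29 in control 2, 1.23 in MTX 1, 1.33 in MTX 2 and 1.26 in the IgG list, whose background library is that of MTX 1.

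Chromosome 11 also held more intervals per Mb than any other autosome in all 5 lists. KDM6A binding as the whole cause is argued against by the IgG library, where the density ratio was 3.78, above the 1.49 reached by any other autosome in any library. Gene density is argued against by chromosome 7, with 1.71 times the protein-coding genes per Mb of the other autosomes against 1.62 for chromosome 11, since its interval density ratio reached only 0.898. Extra copies of chromosome 11 in the cultured cells may account for the pattern: the lowest background ratio was 1.23, above the 1.09 reached by other autosomes, and immunoprecipitated reads per kb were 1.04 to 1.06 times those of the other autosomes, where single autosomes reached 1.02. The rise was thus far smaller in the immunoprecipitated reads, median folds on chromosome 11 were lower (1.21 to 1.37 against 1.45 to 1.66), and reads outside listed intervals were not analysed here, so a copy gain remains a hypothesis.

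Pluripotency genes carried intervals more often than other genes in control 1 and MTX 1. KDM6A binding as the whole cause in MTX 1 is argued against by IgG, where the log2 odds ratio of the list was 3.11, though IgG is 1 library with the same background library as MTX 1; in control 1, which has another background, it stays open, with 0.40 left without intervals that overlap IgG. MTX as the whole cause also stays open: control 1 passed at 1.99, but not in 4 alternatives (0.40 to 1.41, exact test, adjusted p = 0.312 to 0.995), and MTX 2, which goes against it, had 0.73 (0.15 to 1.09 over alternatives) but is 1 library. A difference between the libraries numbered 1 and 2 is a candidate explanation that cannot be told apart from chance here, since the mean log2 odds ratio was 1.86 higher in the libraries numbered 1, but an exact permutation test of 2 against 2 cannot go below p = 0.333. MTX 1 still passed without intervals that overlap IgG (2.52) but not in the better 50% of the list, where the ratio was 1.35. A part due to KDM6A therefore stays open, as does recovery of open chromatin by any antibody, which was not tested.

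Control-only and MTX-only regions were as frequent as in shifted lists when all intervals were used, but stood above them in the stricter settings. Chance overlap of randomly placed lists is argued against by the better 50% of each list, where both classes together exceeded the shifted level by 14.4 SD. Sites that every library catches in part, whatever its group, may account for the excess: both mixed splits had a higher mean ratio to shifted lists than control against MTX in 6 of 6 settings, by 1.02 times or more. The settings are drawn from the same 4 lists, so they are not separate tests. No spread was computed for the differences between splits, and the smallest may lie within it. How many of the regions changed with MTX stays open, since the shifted level is no floor for these classes when many regions are shared by all 4 libraries.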

How the results depend on the processing

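Settings with an adjusted p under 0.05, without chromosome 11 or over whole genes, and all those of the fold test, its replicate block included, were chosen after the data were seen. Of 352 values recomputed under an alternative, 284 kept their direction and side of the threshold or moved by less than the replicate spread or 1.5 times. This count includes values that a setting could not change, such as the log2 odds ratios of the libraries kept when another was left out. It therefore overstates how stable the results were. The ratio of intervals in control to MTX lists was 1.24 as deposited and 1.26 at an adjusted p under 0.05. The better 50% of each list keeps this ratio by construction. The ratio of overlap within to between groups stayed at 0.895 to 0.982. Gene-end ratios stayed at 1.19 to 1.75 in MTX 1, 0.598 to 0.804 in MTX 2 and 0.811 to 0.917 in control 2. In the better 50% of each list, which holds fewer intervals by construction, the mean overlap with IgG was 10.8%, shared regions 178, control-only and MTX-only regions 918 and 818 and genes 66 and 46, the gene-end ratio 0.951 in control 1 and 0.716 in IgG, and the log2 odds ratio of olfactory receptors in MTX 1 rose above 0, to 1.00 (the cause was not tested for these last values). With lists of equal length these were 19.6% overlap, 605 shared and 1208 control-only regions, 98 control-only genes and gene-end ratios of 0.929 in control 1 and 1.13 in IgG (the cause was not tested for the ratios). Requiring 50% overlap, or midpoints within the gene-end windows, gave 17.5% overlap with IgG and 79 and 70 control-only and MTX-only genes. Without intervals that overlap IgG, 667 regions were shared. Wider windows take in more genes: at 3 kb there were 383 and 260 control-only and MTX-only genes, and the IgG gene-end ratio was 1.07, beside 1.16 from 2 kb outside to 0.5 kb inside. An adjusted p under 0.05 gave 17.6% overlap with IgG, 928 shared regions, an IgG gene-end ratio of 1.05 and a log2 odds ratio of 0.42 for olfactory receptors in MTX 1 (the cause was not tested). Without chromosome 11, overlap with IgG was 19.1% and 1183 regions were shared. Over whole genes, which favour long genes, 22 list tests passed, 408 genes were control-only, and the log2 odds ratio of the short olfactory receptor genes was -1.33 in control 1, -0.53 in control 2, -0.44 in MTX 2 and -0.52 in IgG. With each KDM6A library left out, so that 1 library stands for its group, there were 2901 to 3474 shared, 3056 to 30776 control-only and 2603 to 16346 MTX-only regions, 370 to 2741 control-only and 267 to 1475 MTX-only genes, and 0 to 1 lists that shifted between control-only and MTX-only (olfactory receptors, without control 2 or MTX 2). In the fold test edgeR called 0 regions with any library left out, the lone library being assumed to vary like the others, with 43 to 151 regions under an unadjusted p of 0.05 and smallest adjusted p-values of 0.0576 to 0.995. A replicate block called 1 region, lower in MTX cells, at 21506801 to 21523000 on chromosome 11, 33.7 kb from Mdh1 (log2 difference -1.15, edgeR adjusted p = 0.0423; -1.19 and 1.00 without the block; the cause was not tested); its log2 fold was 2.22 in control 1, 0.69 in control 2, 0.03 in MTX 1 and 0.30 in MTX 2. Without MTX as the contrast, edgeR called 0 regions between numbers (108 unadjusted) and 3 in the crossed split (148 unadjusted). Folds of same-numbered libraries did not deviate together at these regions (correlation 0.00453) and the labels do not say what a number marks, so pairing was not established. Within numbers, 34866 regions were in control 1 and not MTX 1 and 15112 the reverse, but 13211 in control 2 and not MTX 2 and 20534 the reverse. At these regions edgeR recovered 68 of 100 simulated 2-fold changes. Smaller changes were not simulated, and how depth limits recovery was not tested.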

Other observations

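The tests in this part were chosen after the result was seen. Genes found in the 2 libraries numbered 1 and neither of those numbered 2 were more frequent than control-only or MTX-only genes: 677 genes had a gene-end interval in control 1 and MTX 1 alone, against 266 ± 20.9 (SD) for shifted lists, and 146 in control 2 and MTX 2 alone, against 236 ± 29.2. Shifting does not keep a list's own share at gene ends. This share was 1.42 and 1.64 times the shifted level in control 1 and MTX 1, and 0.851 and 0.736 times in control 2 and MTX 2. The shifted level is therefore too low for the 677 and too high for the 146, and cannot show that either pair overlapped more or less than by chance. The 677 included Klf5, Mycn, Nr5a2, Tbx3, Tet1 and Tet2 of the pluripotency list, Ccng1, H2ax, Parp1, Polk and Sesn2 of the p53 and DNA damage list, and Ahcy, Folr2, Mat2b and Mtr of the folate and one-carbon list, none of which passed a test between the 677 and the 146 genes (Fisher's exact p = 0.598, 0.598 and 1, adjusted p = 1 for each). Olfactory receptors made up 14 of the 677 and 31 of the 146 genes (Fisher's exact p = 5.87e-15, adjusted p = 9.39e-14 over 16 lists), while vomeronasal receptors, added after the values were seen, had 6 and 4 (exact p = 0.0833).

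Vomeronasal receptors had gene-end intervals in 49 of 353 genes in control 1, 34 in control 2, 41 in MTX 1, 46 in MTX 2 and 38 in IgG. In control 1 this was below the 20.3% of other genes (log2 odds ratio -0.64, exact test, adjusted p = 0.0127 over the 5 libraries), and no other library passed.

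The intervals with the highest folds were narrow and few. A fold of 5 or more was reached by 487 intervals in control 1, 18 in control 2, 30 in MTX 1, 91 in MTX 2 and 53 in IgG, with median widths of 800 to 1200 bp against 2800 to 4000 bp for all intervals. The highest fold of control 1, 217 from 41 reads against 0 in the background, lay within Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, on chromosome 13 at 101766601 to 101767400. In IgG it was 43.6 from 42 reads against 1, at 34805401 to 34805600 on chromosome 19, 1.33 kb from Pank1. These folds rest on 0 or 1 background reads. X held 2 to 20 intervals per library, at 0.00138 to 0.00699 times the density of the autosomes other than 11, and Y held 2 to 5.

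In the fold test, the split of control 1 and MTX 2 against control 2 and MTX 1 called 3 of the shared regions, more than control against MTX, where edgeR called 0. They lay on chromosome 17 at 39841401 to 39850800, 99.7 kb from Esp38 (edgeR adjusted p = 8.09e-09), on chromosome 2 at 98661601 to 98669200, 1030 kb from Lrrc4c (edgeR adjusted p = 3.34e-05), and on chromosome 3 at 5859601 to 5860800, 281 kb from Pex2 (edgeR adjusted p = 0.0211). In the order control 1, control 2, MTX 1 and MTX 2, log2 folds were 0.56, -0.07, -0.08 and 0.31 on chromosome 17. On chromosome 2 they lay close together, at 0.38, 0.20, 0.26 and 0.43, and on chromosome 3 they were 0.58, 0.03, -0.27 and 0.56. The genes are only the nearest protein-coding ones, and other genes and repeats at these positions were not searched. No list of repeat-rich regions was used to remove intervals, and the cause of these calls was not tested.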
